A study of Homo sapiens with 8 samples.

How the data were processed

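The series holds 8 samples of MDA-MB-231 cells stably transduced with lentivirus carrying control shRNA or shRNA against integrin α3. The 2 control and 2 knockdown cultures, called biological replicates in the series description, were each hybridised to an Affymetrix Human Exon 1.0 ST array and summarised at the gene level and at the exon level. Groups and replicate numbers come from the sample titles. Total RNA was isolated with a column kit, depleted of ribosomal RNA and labelled with biotin, per the labels' protocols.

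The deposited values are PLIER intensities on a linear scale, per transcript cluster (22011) and per probeset (287329). Per the labels, they come from Affymetrix Expression Console with the core gene and core exon probesets, and the series description names the Exon Array Computational Tool. Versions, background correction and normalization between arrays are not given in the sources used here. Column medians differ, so the deposited intensities had not been forced to a common distribution. No scanner file was used, and 4 arrays limit the precision of every value.

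Features were named through the platform annotation supplied with the series, with symbols updated through Entrez identifiers or unambiguous synonyms in NCBI RefSeq gene names (assembly GRCh38, used for names only). Of the gene-level features, 14432 had 1 symbol, 2408 several and 5171 no row in that annotation. At the exon level the numbers were 261273, 9155 and 16901. Features with several symbols or none were tested but not named, and a gene with several transcript clusters is represented by its brightest one. No coordinates are given, since the files name no genome build.

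Intensities were transformed as log2(value + 16), and the authors' normalization was kept. Features in the lower 40% by mean over all 4 arrays were left out. Knockdown and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, group as the only term, 2 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 16) scale, which understates changes of dim genes. Exon-level values were tested the same way. Exon usage was tested with limma's diffSplice and its Simes test in genes with at least 3 tested probesets. For 31 gene lists, calls were counted over all genes and adjusted over the list alone. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. Values were handled with the data.table package (version 1.17.8), and plots drawn with matplotlib 3.10.9 in Python 3.11.15.

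The lists covered integrin subunits, basement membrane, focal adhesion and tetraspanins, the prostaglandin pathway, matrix proteases, matrix glycoproteins, inflammatory cytokines, growth factor ligands, receptor tyrosine kinases, mesenchymal and epithelial genes, YAP, WNT and TGF-beta targets, interferon-stimulated genes, both cell cycle phases, p53 targets, hypoxia and glycolysis, cholesterol synthesis, unfolded protein stress, immediate early genes, splicing factors, mRNA decay factors, histones, ribosomal proteins, the respiratory chain, genes linked to ITGA3 by earlier work, and luminal, fibroblast, leukocyte and neural markers. Lists, tests, most alternative settings and the rule for named genes were fixed before the data were examined. By that rule the text names ITGA3, the linked genes (some are not reported here), the 10 largest rises and 10 largest falls among called genes with 1 symbol and with both knockdown arrays outside the control range, up to 4 members per list with the smallest p, the probesets of ITGA3 and PTGS2, the 10 genes with the smallest exon-usage p, and listed genes among those called for exon usage. Near-identical copies are named as uncertain. Where a list has several such members, the text gives some of them.

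Each step was tested on simulated data with the real means and fitted spread. In the gene-level comparison over 13207 features, limma recovered 31% of genes changed 1.5-fold and 86% of those changed 2-fold, with 10 false calls among 127. It made 0 calls without any change, where the real comparison made 2807 at the adjusted threshold and 4726 at an unadjusted p under 0.05. The simulated features varied independently, with no shift shared across an array. The 0 calls therefore do not show how many of the 2807 reflect the knockdown. Over 12211 genes, diffSplice recovered 34% of genes with 1 probeset changed 2-fold and 100% at 8-fold, with 69.2% of its calls false. The simulated genes did not change beyond that 1 probeset. A test of each probeset against the mean of the other probesets of its gene, with its own moderated variance, recovered 11% and 92% with 5.50% false. It was added after the self-test and is reported beside diffSplice.

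The alternatives were another offset, no filter or a stricter one, other variance models, quantile normalization, centring on the median, the replicate number as a block, leaving out each array, a plain per-gene test, limma's treat, other list tests and other exon-usage tests. The closing section gives their effect.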

Results

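RNA of MDA-MB-231, a human triple-negative breast cancer cell line, was measured on Affymetrix Human Exon 1.0 ST arrays, which carry separate probesets for most exons of a gene. The cells carried a lentiviral short hairpin RNA (shRNA), either a control hairpin or a hairpin against the integrin α3 subunit, with 2 biological replicates in each group. The 4 arrays were summarised at the gene level, as 22011 transcript clusters, and again at the exon level, as 287329 probesets. These summaries make up the 8 samples of the series, so the exon-level samples are not further replicates. All values are PLIER intensities on a linear scale, given as mean ± SD of n = 2 arrays per group, and the number of arrays limits their precision. Median gene-level intensity was 177 and 186 in the controls and 168 and 171 in the knockdown arrays. Across transcript clusters the log2 values correlated at r = 0.990 between the controls, 0.992 between the knockdown arrays, and 0.961 to 0.968 between arrays of different groups. Clusters are not independent replicates.

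The comparison asked which transcripts differ between cells with the α3 hairpin and cells with the control hairpin. The samples include no rescue of α3 and no group labelled with a different α3 hairpin. Loss of α3 therefore cannot be told apart from other effects of the hairpin or differences between the transduced cells. ITGA3 (transcript cluster 3726154), the target of the hairpin, measured 3480 and 3529 in the controls and 619 and 644 in the knockdown arrays. It fell by 2.44 ± 0.073 (SE) on the log2 scale, or 5.44-fold (adjusted p = 8.04e-05, limma with Benjamini-Hochberg adjustment). ITGB1, the β1 partner of α3, went from 3267 ± 134 to 2899 ± 83.6 and did not pass the test (adjusted p = 0.168). PTGS2 (transcript cluster 2448382), which encodes the inducible prostaglandin synthase cyclooxygenase-2, had the largest difference of the genes with 1 symbol tested, from 1207 ± 99.5 to 8.40 ± 0.288 (log2 difference -5.65 ± 0.116 (SE), adjusted p = 3.73e-05). Since its knockdown values lie below the offset of 16 added before the logarithm, this log2 difference understates the ratio.

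Among 15 genes linked to α3 integrin by earlier work, 11 were tested, 6 fell, 0 rose and 5 did not pass. Adjusted over the list alone, 6 fell and 1 rose. After quantile normalization or centring, 4 fell and 1 rose. Besides ITGA3 and PTGS2, FN1, which encodes fibronectin, fell from 1959 ± 103 to 1267 ± 13.3 (log2 difference -0.62, adjusted p = 0.00496). POU3F2, a POU-domain transcription factor, fell from 241 ± 9.15 to 154 ± 29.7 (adjusted p = 0.0322), CD151, the tetraspanin partner of α3β1, from 2108 ± 140.0 to 1658 ± 70.9 (adjusted p = 0.0345), and IL1A from 142 ± 5.61 to 98.1 ± 0.438 (adjusted p = 0.0357). In controls and knockdown, BMP1 measured 146 ± 2.72 and 190.4 ± 11.51 (adjusted p = 0.0696), CCN1 3630.5 ± 175 and 4132 ± 155 (adjusted p = 0.154), the gelatinase gene MMP9 197 ± 11.8 and 214 ± 5.78 (adjusted p = 0.497) and FBLN2 271 ± 27.2 and 292 ± 126 (adjusted p = 0.936), none of which passed. MMP2 lay among the dim features at 48.1 ± 2.03 and 59.9 ± 3.06, and LAMA3 was read only at the exon level, where its median probeset did not pass (log2 difference 0.15 ± 0.16 (SE), adjusted p = 0.603). The list did not pass in camera, limma's test of a gene list against the other genes (adjusted p = 0.111), but was lower without knockdown replicate 1 (0.00979), on exon-level medians (0.0164) and by limma's fry, which does not compare it with other genes (0.00834). Its members include ITGA3, the target itself, and come partly from work on α3 in these or similar cells. Its count and list tests are therefore not independent evidence of a direction. The IL1A call was lost without any 1 of the 4 arrays (adjusted p = 0.0685 to 0.173), without the filter (0.0586) and after quantile normalization (0.0616) or centring (0.0961). That of POU3F2 was lost without control replicate 1 (0.0704), control replicate 2 (0.0935) or knockdown replicate 2 (0.180) or the filter (0.0696). That of CD151 was lost without control replicate 1 (0.0856), knockdown replicate 1 (0.0970), knockdown replicate 2 (0.196), the filter (0.0673) or the intensity trend (0.0561) and after quantile normalization (0.0617) or centring (0.145). BMP1 passed without the trend (0.0458), with the replicate numbers as a block (0.0402) and after quantile normalization (0.0305) or centring (0.0330).

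**Figure D1:**
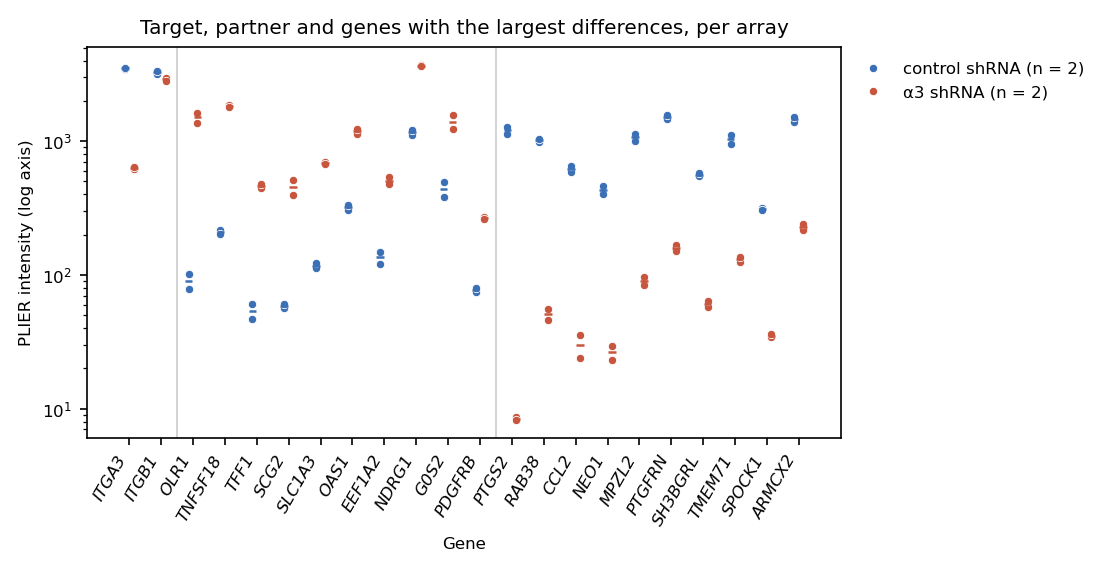
Gene-level PLIER intensity (log axis) of ITGA3, ITGB1, the 10 genes with the largest rises and the 10 with the largest falls. Points are single arrays and bars are group means (n = 2 per group). Both knockdown arrays lie on one side of both controls for every gene shown, which the selection rule required of the 10 rises and 10 falls. ITGA3 lies at 619 and 644 against 3480 and 3529, and ITGB1, also apart, did not pass limma.

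Among all gene-level clusters, more fell than rose, though not after centring each array on its median. The largest rises were in OLR1, the lectin-like receptor for oxidised low-density lipoprotein, from 89.8 ± 16.7 to 1506 ± 185 (log2 difference 3.85 ± 0.143 (SE), adjusted p = 0.000145), and in TNFSF18, the ligand of the receptor GITR, from 211 ± 10.8 to 1832 ± 52.8 (3.03 ± 0.083 (SE), adjusted p = 8.04e-05). TFF1, a secreted trefoil peptide, rose from 54.2 ± 9.92 to 461 ± 20.03, the granin SCG2 from 58.6 ± 2.87 to 454 ± 78.4 and the glutamate transporter SLC1A3 from 118 ± 6.61 to 687 ± 18.4. OAS1, an interferon-induced enzyme, rose from 322 ± 19.4 to 1185 ± 72.9, NDRG1 from 1161 ± 60.03 to 3674 ± 69.6, the lipase inhibitor G0S2 from 442 ± 79.2 to 1396 ± 238 and PDGFRB, a platelet-derived growth factor receptor, from 77.0 ± 4.21 to 266 ± 6.43. EEF1A2 rose from 135 ± 19.6 to 506 ± 42.1, but it is named as uncertain because of its close similarity to EEF1A1. Adjusted p ranged from 8.04e-05 (TNFSF18) to 0.00282 (G0S2) over these 10 genes.

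After PTGS2, the largest falls were in RAB38, a Rab GTPase of melanosome transport, from 1015 ± 41.7 to 51.1 ± 6.79 (log2 difference -3.94 ± 0.113 (SE), adjusted p = 8.04e-05), and in CCL2, the monocyte chemoattractant, from 619.6 ± 46.9 to 29.8 ± 8.44 (-3.81 ± 0.157 (SE), adjusted p = 0.000195). The receptor gene NEO1 fell from 433 ± 44.9 to 26.4 ± 4.37 and MPZL2, an immunoglobulin-family adhesion protein, from 1066 ± 91.4 to 90.7 ± 8.35. PTGFRN, a membrane partner of tetraspanins, fell from 1514 ± 83.6 to 160.1 ± 11.7, SH3BGRL from 561 ± 19.9 to 60.7 ± 4.33 and TMEM71 from 1029.8 ± 111 to 131 ± 7.82. The proteoglycan gene SPOCK1 fell from 312 ± 7.55 to 35.0 ± 1.24 and ARMCX2 from 1459.9 ± 84.0 to 229.7 ± 16.3. The adjusted p of these 7 genes named after CCL2 lay between 8.04e-05 (PTGFRN) and 0.000234 (SPOCK1). All 20 genes kept their call in every alternative setting of the limma fit that tested them.

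Of 13207 transcript clusters tested by limma, 791 were higher and 2016 lower in knockdown at an adjusted p under 0.05. A change of at least 2-fold on the offset scale was seen in 61 of the higher and 146 of the lower clusters. Among 9233 genes with 1 symbol, 562 were higher and 1547 lower. Both knockdown arrays lay above both controls, or both lay below them, in 61.8% of clusters, where interchangeable arrays would give 33.3%. Both knockdown arrays also had lower medians than both controls, and a shift shared across clusters can raise that share by itself. The share therefore does not show how many clusters reflect the knockdown. This separation held for every gene named here as risen or fallen. The selection rule required it of the largest rises and falls, and the others had passed limma on the same arrays, so it is not independent evidence. The split into higher and lower clusters depended on scaling, with 1351 higher and 1674 lower after quantile normalization and 1586 higher and 1457 lower after centring each array on its median. With 1 array fewer, 166 were higher and 632 lower without knockdown replicate 2, 391 and 693 without knockdown replicate 1, and 504 and 1906 without control replicate 1. With 1 array left in a group, that array is assumed to vary like the other group. Without control replicate 2, 909 were higher and 1349 lower. Without the filter on dim features 485 were higher and 1511 lower, and with the replicate block 1324 and 2741.

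**Figure D2:**
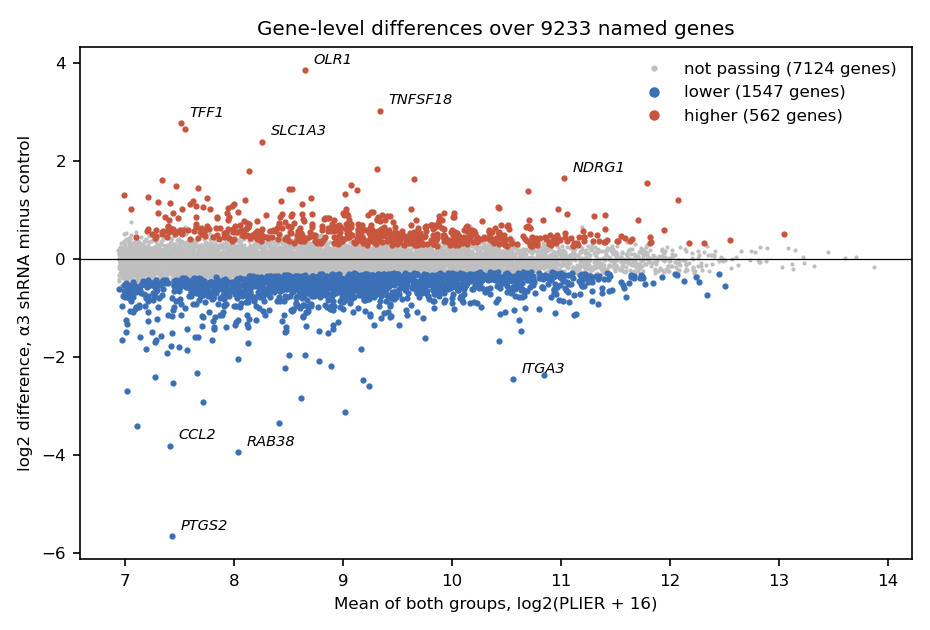
Difference between groups (log2, α3 shRNA minus control) against the mean level, log2(PLIER + 16), for the 9233 tested genes with 1 symbol. Each point is a gene, coloured where it passed limma's adjusted p of 0.05, with 562 higher and 1547 lower, and PTGS2 lies lowest at -5.65.

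Cholesterol synthesis genes fell together. Of 16 tested, 13 fell, 0 rose and 3 did not pass, and 15 fell when adjusted over the list alone. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell from 768 ± 19.0 to 259.6 ± 6.72 (log2 difference -1.51, adjusted p = 0.000563), DHCR7, which makes cholesterol in the last step of one branch, from 2036 ± 16.6 to 927 ± 25.3 (adjusted p = 0.000920), lanosterol synthase LSS from 978 ± 0.327 to 453 ± 4.08 (adjusted p = 0.00113) and the sterol reductase gene TM7SF2 from 672 ± 6.83 to 376 ± 0.368 (adjusted p = 0.00291). The list was lower than the other genes in camera with a preset correlation of 0.01 (adjusted p = 8.41e-08, but adjusted p = 0.842 with an estimated correlation). Its median log2 difference was -0.635, and 13 members fell under both other scalings.

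Genes of hypoxia and glycolysis rose more often than they fell. Of 25 tested, 12 rose, 3 fell and 10 did not pass, and the counts were the same adjusted over the list alone. NDRG1 rose as given above (log2 difference 1.65, adjusted p = 0.000273), and BNIP3, a mitophagy receptor, rose from 1388 ± 52.8 to 2859 ± 524 (log2 difference 1.02, adjusted p = 0.00519). The members did not move one way, since VEGFA, which encodes the angiogenic factor, fell from 1619 ± 26.2 to 862 ± 10.4 (log2 difference -0.90, adjusted p = 0.00169) and LOX, the collagen cross-linking enzyme, from 1151 ± 81.9 to 441 ± 12.6 (log2 difference -1.35, adjusted p = 0.000920). As a set the list was higher in camera (adjusted p = 0.000554, but adjusted p = 0.842 with an estimated correlation).

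Some immediate early genes of growth factor signalling fell. Of 25 tested, 7 fell, 0 rose and 18 did not pass, with 11 lower adjusted over the list alone. SPRY2, a feedback inhibitor of receptor signalling, fell from 2086 ± 98.0 to 1233 ± 47.8 (log2 difference -0.75, adjusted p = 0.00343), and the AP-1 genes JUNB from 531 ± 18.6 to 339 ± 4.63 (adjusted p = 0.00655) and JUN from 1426 ± 7.99 to 1052 ± 53.5 (adjusted p = 0.0138). KLF6 fell from 1352 ± 138 to 876 ± 50.1 (adjusted p = 0.0102). Camera placed the list lower than other genes (adjusted p = 0.0225, but adjusted p = 0.842 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0927) and without knockdown replicate 2 (0.0546), and the JUN call without knockdown replicate 1 (0.0912) or 2 (0.0581) and the KLF6 call without knockdown replicate 2 (0.0575). No other list passed camera at the gene level in the main fit. On exon-level medians, a test chosen after the data were seen, camera called 4 lists, cholesterol synthesis (adjusted p = 6.23e-10), hypoxia and glycolysis (0.000143), splicing factors (0.00788) and the genes linked to α3 (0.0164), while the immediate early list did not pass (0.0506). At the gene level 0 lists passed with an estimated correlation, for which 4 arrays leave 2 residual degrees of freedom, while 6 lists had an unadjusted p under 0.05 with the preset correlation. The falls numbered 6 after quantile normalization and 5 after centring.

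**Figure D3:**
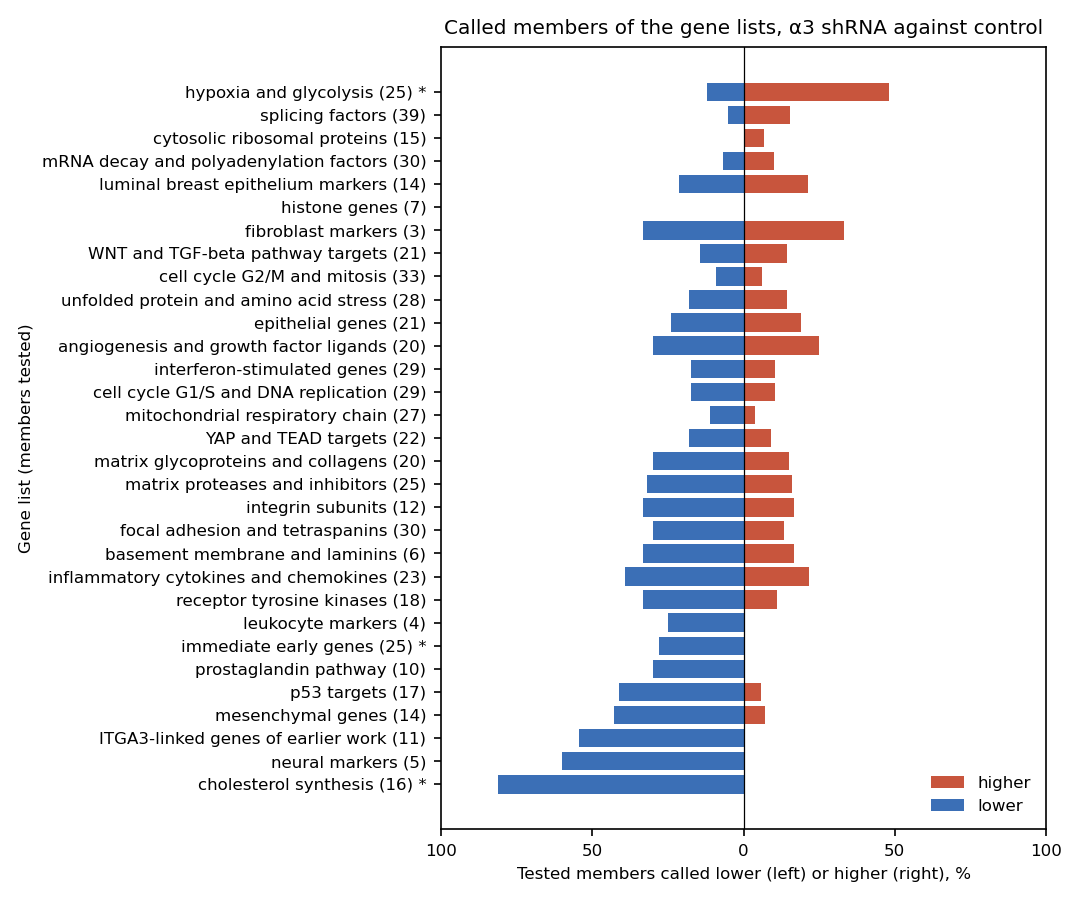
Share of tested members of each gene list (in %, number tested in parentheses) called higher (right) or lower (left) by limma in α3 shRNA against control cells. An asterisk marks a camera adjusted p under 0.05 with the preset correlation. Cholesterol synthesis has 13 of 16 members lower, and hypoxia and glycolysis 12 of 25 higher.

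Adhesion and matrix genes moved in both directions. Of 12 integrin subunits tested, 2 rose, 4 fell and 6 did not pass (3 and 4 adjusted over the list alone). Besides ITGA3, the laminin receptor subunit ITGA6 fell from 2141 ± 16.8 to 1636 ± 2.55 (adjusted p = 0.0151) and ITGB2 from 372 ± 30.6 to 266 ± 5.13 (adjusted p = 0.0253), while ITGA2, a collagen receptor subunit, rose from 1532 ± 38.5 to 1965 ± 109 (adjusted p = 0.0260). The integrin list had a positive median (0.06), a negative mean (-0.16) and an upward camera direction (adjusted p = 0.959). It includes ITGA3, the target of the hairpin, and was not tested without it. Of 30 focal adhesion and tetraspanin genes, 4 rose, 9 fell and 17 did not pass (5 and 12 adjusted over the list alone, camera adjusted p = 0.387). NEDD9, a focal adhesion scaffold, rose from 123 ± 3.87 to 316 ± 19.3 (adjusted p = 0.00193), kindlin-1 (FERMT1) fell from 437 ± 54.6 to 174 ± 13.6 (adjusted p = 0.00284), TGFB1I1 fell from 648 ± 16.2 to 404 ± 7.83 (adjusted p = 0.00496), and PTK2, the focal adhesion kinase, rose from 1597 ± 113 to 2127 ± 38.2 (adjusted p = 0.0187). Of 6 basement membrane genes, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.959), with LAMB2 falling from 1235 ± 27.3 to 865 ± 56.7 (adjusted p = 0.0105) and COL4A1 rising from 247 ± 39.4 to 422 ± 15.4 (adjusted p = 0.0118). Calls lost without either knockdown replicate 1 or 2 were those of ITGA6 (adjusted p = 0.0829 and 0.0971), ITGB2 (0.138 and 0.132), ITGA2 (0.163 and 0.0841) and PTK2 (0.0950 and 0.0866), and LAMB2 (0.0771) and COL4A1 (0.0666) lost theirs without knockdown replicate 2. The ITGB2 call was also lost without control replicate 2 (0.0653) and the ITGA2 call without control replicate 1 (0.0639) or the filter (0.0519). LAMA5, the other basement membrane gene called lower, lost its call without control replicate 2 and without knockdown replicate 1 or 2. It also lost the call without the filter (adjusted p = 0.0644) or the intensity trend (0.0511) and after centring (0.0742). After quantile normalization (after centring in parentheses), rises and falls numbered 3 and 3 (4 and 3) for integrins, 5 and 6 (5 and 3) for focal adhesion and 1 and 2 (1 and 1) for basement membrane genes.

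Matrix proteins and proteases also moved in both directions. Of 20 matrix glycoproteins and collagens, 3 rose, 6 fell and 11 did not pass (4 and 6 adjusted over the list alone). CCN3 fell from 773 ± 3.42 to 187 ± 8.20 (log2 difference -1.96, adjusted p = 0.000243), TNC, which encodes tenascin-C, from 341 ± 58.8 to 51.4 ± 8.85 (adjusted p = 0.00109), the fibril-associated collagen gene COL12A1 from 344 ± 58.3 to 83.7 ± 5.03 (adjusted p = 0.00144) and fibulin-1 (FBLN1) from 318 ± 13.5 to 156 ± 8.30 (adjusted p = 0.00362). The list's median was 0.02, its mean -0.33 and its camera direction downward (adjusted p = 0.959). Of 25 matrix proteases and inhibitors, 4 rose, 8 fell and 13 did not pass (6 and 9 adjusted over the list alone, camera adjusted p = 0.752). The rises and falls numbered 6 and 8 after quantile normalization, 6 and 6 after centring. The interstitial collagenase gene MMP1 fell from 4175 ± 577 to 794 ± 13.5 (log2 difference -2.36, adjusted p = 0.000243), stromelysin-1 (MMP3) from 296 ± 24.7 to 100.0 ± 9.12 (adjusted p = 0.00197) and cathepsin B (CTSB) from 1800.5 ± 2.08 to 1019.5 ± 22.6 (adjusted p = 0.00218).

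Among secreted signals and their receptors, the prostaglandin pathway had 3 of 10 tested genes lower, 0 higher and 7 not passing (3 and 1 adjusted over the list alone, camera adjusted p = 0.478). Under both other scalings 2 of these were higher and 3 lower. The median log2 difference of the list went from -0.094 to 0.003 after quantile normalization and 0.004 after centring. Of the 18 pathway genes with a gene-level cluster, the rest were left out as dim. Among them, and named after its value was seen, PLA2G4A measured 50.4 ± 4.39 in controls and 10.7 ± 1.10 in knockdown (limma without the filter, adjusted p = 0.0143). The others left out did not pass that fit. With PTGS2, the prostaglandin E2 receptor gene PTGER4 fell from 518 ± 6.80 to 240.0 ± 8.76 (adjusted p = 0.00186) and the prostaglandin E synthase gene PTGES from 1562 ± 166 to 824 ± 0.288 (adjusted p = 0.00334). Of 23 inflammatory cytokine and chemokine genes, 5 rose, 9 fell and 9 did not pass (5 and 10 adjusted over the list alone, camera adjusted p = 0.473). With CCL2, the cytokine genes IL11 from 761 ± 26.1 to 302 ± 5.76 (adjusted p = 0.000920) and LIF from 1119.8 ± 19.2 to 502 ± 14.9 (adjusted p = 0.00109) fell, while PTX3, a long pentraxin, rose from 2831 ± 7.47 to 6528 ± 273 (adjusted p = 0.000920). Of 20 angiogenesis and growth factor ligand genes, 5 rose, 6 fell and 9 did not pass (6 and 8 adjusted over the list alone, camera adjusted p = 0.959), with endothelin-1 (EDN1) falling from 1023 ± 108 to 447 ± 2.75 (adjusted p = 0.00182) and neuropilin-1 (NRP1) from 1214 ± 37.2 to 659 ± 18.8 (adjusted p = 0.00218). Of 18 receptor tyrosine kinases, 2 rose, 6 fell and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.710). The ephrin receptor gene EPHA4 fell from 403 ± 9.09 to 56.2 ± 0.0634 (adjusted p = 0.000195) and AXL from 4174 ± 61.5 to 2911 ± 4.50 (adjusted p = 0.00691), whereas EGFR, the epidermal growth factor receptor, rose from 876 ± 29.4 to 1391 ± 52.4 (adjusted p = 0.00449). After quantile normalization (after centring in parentheses), rises and falls numbered 5 and 7 (5 and 7) for cytokine genes, 6 and 6 (6 and 5) for growth factor ligand and 2 and 4 (2 and 4) for receptor tyrosine kinase genes.

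Mesenchymal genes were lower in 6 of 14 tested, higher in 1 and did not pass in 7, also adjusted over the list alone (camera adjusted p = 0.387). The transcription factor gene SNAI2 fell from 1079 ± 20.4 to 515 ± 37.9 (adjusted p = 0.00178) and CDH11, a mesenchymal cadherin, from 2516 ± 75.8 to 1230.0 ± 28.3 (adjusted p = 0.00118). Of 21 epithelial genes, 4 rose, 5 fell and 12 did not pass (5 and 5 adjusted over the list alone, camera adjusted p = 0.443). Among tight junction genes of this list, CLDN1 rose from 1010.4 ± 97.9 to 2674 ± 109.6 (adjusted p = 0.00101) and CLDN4 from 311 ± 44.5 to 801 ± 51.4 (adjusted p = 0.00218), and CLDN7 fell from 604 ± 19.5 to 352 ± 19.1 (adjusted p = 0.00450), as did the keratin gene KRT19, from 4008 ± 277 to 2349.5 ± 9.93 (adjusted p = 0.00359). Of 22 YAP and TEAD targets, 2 rose, 4 fell and 16 did not pass (3 and 6 adjusted over the list alone), with ANKRD1 rising from 2053 ± 269.9 to 5998 ± 239 (adjusted p = 0.00110) and IGFBP3 falling from 785 ± 20.2 to 498 ± 27.1 (adjusted p = 0.00583). Of 21 WNT and TGF-beta targets, 3 rose, 3 fell and 15 did not pass (5 and 3 adjusted over the list alone, camera adjusted p = 0.111). The rises and falls numbered 5 and 2 after quantile normalization, 5 and 1 after centring. The inhibitors of differentiation ID1 from 734 ± 65.6 to 1412 ± 30.7 (adjusted p = 0.00273) and ID3 from 349.8 ± 11.2 to 728 ± 11.1 (adjusted p = 0.00166) rose, and LEF1 fell from 253 ± 6.59 to 145 ± 2.21 (adjusted p = 0.00655). After quantile normalization (after centring in parentheses), rises and falls numbered 1 and 5 (1 and 5) for mesenchymal genes, 5 and 4 (7 and 5) for epithelial genes and 4 and 5 (4 and 4) for YAP and TEAD targets.

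Of 17 p53 targets, 7 fell, 1 rose and 9 did not pass, also adjusted over the list alone (camera adjusted p = 0.473). CCNG1 fell from 853 ± 0.827 to 466 ± 13.3 (adjusted p = 0.00246), TP53I3 from 521 ± 28.2 to 260.1 ± 18.6 (adjusted p = 0.00327) and BAX, which promotes apoptosis, from 833 ± 7.78 to 573 ± 9.56 (adjusted p = 0.00766), a call lost without knockdown replicate 2 (adjusted p = 0.0623). Of 28 unfolded protein and amino acid stress genes, 4 rose, 5 fell and 19 did not pass (5 and 9 adjusted over the list alone). The cystine transporter gene SLC7A11 rose from 691 ± 39.5 to 1331 ± 59.6 (adjusted p = 0.00227) and CHAC1 from 422 ± 6.95 to 836 ± 67.5 (adjusted p = 0.00260), and PHGDH, the first enzyme of serine synthesis, fell from 1376 ± 74.7 to 734 ± 3.96 (adjusted p = 0.00218). Of 29 interferon-stimulated genes, 3 rose, 5 fell and 21 did not pass (3 and 6 adjusted over the list alone), with OAS1 higher and MX2 lower, from 214 ± 12.8 to 79.7 ± 12.6 (adjusted p = 0.00377). After quantile normalization (after centring in parentheses), rises and falls numbered 2 and 7 (2 and 6) for p53 targets, 5 and 5 (5 and 4) for stress and 5 and 4 (5 and 4) for interferon-stimulated genes.

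Genes of proliferation and of core RNA, protein and energy metabolism mostly did not pass. The same held over all 9233 genes with 1 symbol tested, of which 562 were higher and 1547 lower. Of 29 G1/S and DNA replication genes, 3 rose, 5 fell and 21 did not pass (3 and 7 adjusted over the list alone), with GINS3, a replication helicase subunit, falling from 656 ± 31.0 to 330.2 ± 4.36 (adjusted p = 0.00227). Of 33 G2/M and mitosis genes, 2 rose, 3 fell and 28 did not pass (1 and 1 adjusted over the list alone), with BIRC5, which encodes survivin, falling from 2015 ± 85.1 to 1281 ± 6.46 (adjusted p = 0.00429). Of 39 splicing factors, 6 rose, 2 fell and 31 did not pass, also adjusted over the list alone (camera adjusted p = 0.0816). On exon-level medians camera placed 46 splicing factors higher than other genes (adjusted p = 0.00788). SRSF9 rose from 3196 ± 37.1 to 4821 ± 93.7 (adjusted p = 0.00496), and KHDRBS3 from 748 ± 23.3 to 286 ± 18.7 (adjusted p = 0.00105) and RBFOX2 from 1300.3 ± 50.2 to 837 ± 8.75 (adjusted p = 0.00483) fell. Of 30 mRNA decay and polyadenylation factors, 3 rose, 2 fell and 25 did not pass (1 and 1 adjusted over the list alone), with ZFP36L1, which binds AU-rich elements, falling from 2009.5 ± 255 to 1274 ± 59.2 (adjusted p = 0.0105). Of 27 respiratory chain genes, 1 rose, 3 fell and 23 did not pass (1 and 3 adjusted over the list alone), with the complex I subunit gene NDUFA9 falling from 2273 ± 134 to 1135 ± 44.2 (adjusted p = 0.00177). Of 15 cytosolic ribosomal protein genes tested at the gene level, 1 rose, 0 fell and 14 did not pass (0 and 0 adjusted over the list alone). The rise, in RPS25, was lost without the filter (adjusted p = 0.0697) or the intensity trend (0.0586). It was also lost without control replicate 1 and without knockdown replicate 1 or 2. All 7 histone genes tested did not pass, also adjusted over the list alone. After quantile normalization (after centring in parentheses), rises and falls numbered 4 and 4 (8 and 4) for G1/S genes, 4 and 2 (5 and 1) for G2/M, 4 and 2 (5 and 2) for mRNA decay and 2 and 3 (2 and 2) for respiratory chain genes.

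Markers of other cell types gave no uniform shift. Of 14 luminal breast epithelium markers, 3 rose, 3 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.959). TFF1 rose while SPDEF fell from 477 ± 15.7 to 294 ± 35.1 (adjusted p = 0.0105), a call lost without knockdown replicate 1 (adjusted p = 0.0625). Of 3 fibroblast markers tested, PDGFRB rose, FBLN1 fell and 1 did not pass, of 4 leukocyte markers 1 fell, and of 5 neural markers 3 fell, POU3F2 among them, with the same counts adjusted over each list alone. Of these 3 neural calls, 0 were kept without knockdown replicate 2 (adjusted p = 0.0784 to 0.180), 1 without any 1 of the other arrays or without the filter, and 2 after centring. The camera directions of the YAP, unfolded protein, G1/S, G2/M and mRNA decay lists were upward although their medians and means were negative, and that of the luminal list was upward with a negative median and a positive mean. After quantile normalization the directions of the YAP and unfolded protein lists were downward, and after centring that of the luminal list was. The leukocyte call, that of CD68, was lost under both scalings and without any 1 array. It was also lost without the filter (adjusted p = 0.0661) or the intensity trend (0.0629). Over the YAP, interferon, G1/S, G2/M, unfolded protein, mRNA decay, neural, histone, ribosomal and respiratory chain lists, camera's adjusted p lay between 0.473 (neural) and 0.988 (interferon).

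At the exon level, 172397 probesets were tested, of which 2292 were higher and 5599 lower in knockdown (limma, adjusted p under 0.05). After quantile normalization 3416 were higher and 4861 lower, and after centring 3348 and 4137. The counts depended far more on the filter and the variance model, with 43 higher and 120 lower without the filter on dim features, 379 and 1314 without the intensity trend, and 10755 and 18202 with the replicate block. All 39 probesets of ITGA3 were tested. Of these, 37 were lower, with a median log2 difference of -2.44 over all 39, and 2 did not pass, among them probeset 3726156 at 651 ± 349 in controls and 759 ± 384 in knockdown. Of 18 PTGS2 probesets, 13 were bright enough over all arrays to test, and 12 of these were lower. Among those left out, probesets 2448384, 2448386 and 2448397 measured 298, 377 and 731 in controls and 3.18, 0.357 and 0.00846 in knockdown. The others left out, 2448392 and 2448393, measured 8.57 and 10.9 in controls. The knockdown mean lay under 16 in 6 of the 13, and probeset 2448391 fell from 2333 ± 162 to 19.1 ± 3.70. Probesets 2448402 and 2448403 differed less, with 829 ± 178 against 375 ± 40.8 and 201 ± 1.75 against 129 ± 14.3, the latter not passing (adjusted p = 0.201). Without 1 array, higher probesets numbered 753 without knockdown replicate 2 and 848 without control replicate 1, and lower ones 2161 without control replicate 1, 2303 without control replicate 2, 3257 without knockdown replicate 1 and 2590 without knockdown replicate 2. Gene-level and median exon-level log2 differences correlated at Pearson r = 0.970 and Spearman rho = 0.957 across 8633 genes, which are not independent replicates.

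**Figure D4:**
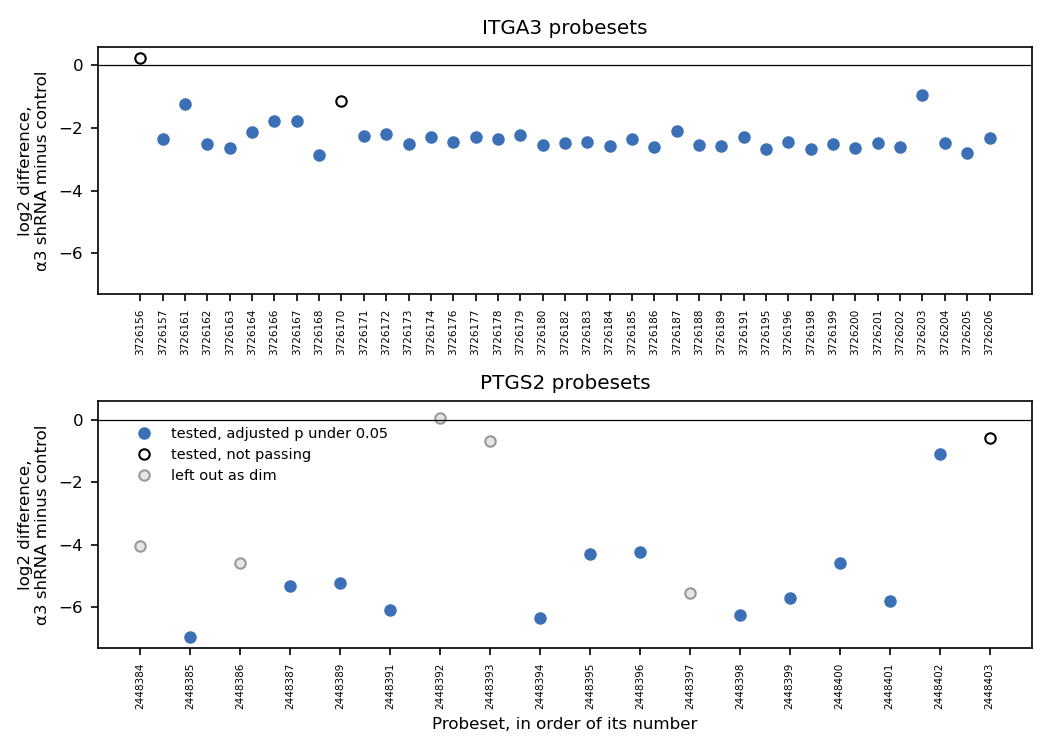
Exon-level log2 difference (α3 shRNA minus control) of each ITGA3 and PTGS2 probeset, in order of probeset number, from 2 arrays per group. Filled blue points passed limma's adjusted p of 0.05, open black points did not, and grey points were left out as dim. For ITGA3, 37 of 39 probesets were lower, with a median of -2.44, and PTGS2 probesets 2448402 and 2448403 fell less than most others.

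The exon-level summaries also asked whether exon usage within genes differed between the groups. limma's diffSplice, which sets each probeset against the other probesets of its gene, called 428 of 12211 genes (Simes test per gene, Benjamini-Hochberg adjusted p under 0.05). On simulated data with known answers, however, 301 of its 435 calls were false. A test with each probeset's own variance, chosen after seeing that, called 49 genes, 45 of them shared, and made 6 false calls among 109 in the simulation. The simulation held no genes that moved as a whole, whereas only 5 of the 45 had a median log2 difference under 0.5 in size. Its false share therefore need not hold for these 45 genes. Of the 10 genes with the smallest diffSplice p, 7 passed both tests. Probeset positions within genes were not available. A call therefore shows a probeset that departs from its gene, and not that splicing changed. PTGS2 had the smallest p with own variances, its probeset 2448403 going from 201 ± 1.75 to 129 ± 14.3 where the gene's median log2 difference was -5.32 (adjusted p = 3.14e-09 and 0.000346, by diffSplice and with own variances). In knockdown, however, PTGS2 measured 8.40 at the gene level, and 6 of its 13 tested probesets averaged under 16. Whether the signal left at probeset 2448403 comes from PTGS2 transcript cannot be told, so this call does not show changed usage. In EPB41L3, which encodes a membrane skeleton protein, probeset 3797050 fell from 1134 ± 171 to 2.30 ± 3.25, beyond the gene's median of -2.60 (3.34e-10 and 0.00106). In the receptor-type phosphatase gene PTPRN2, probeset 3081897 fell from 669 ± 123 to 7.44 ± 5.31 against a gene median of -0.21 (1.18e-06 and 0.00143). NEO1 probeset 3601131 went from 226 ± 14.6 to 179 ± 19.7 where the gene's median was -3.48 (7.65e-12 and 0.00418), LRIG1 probeset 2680685 from 323 ± 13.4 to 516 ± 16.9 against -1.47 (3.14e-09 and 0.00900), POU3F2 probeset 2918407 from 486 ± 59.5 to 18.4 ± 7.78 against -0.61 (6.62e-08 and 0.0105), and GNPTG probeset 3643814 from 146 ± 59.0 to 717 ± 104 against -0.33 (2.25e-10 and 0.0219).

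ITGA3 (probeset 3726156), COL12A1 (2961280) and GALC (3575170) were called by diffSplice but not with own variances (adjusted p = 0.0634, 0.195 and 0.238). Of the 428 genes 37 were on a fixed list, and 5 of these, PTGS2, CCN3, TNC, POU3F2 and TFF1, passed both tests. TNC probeset 3222254 measured 651 ± 9.20 and 738 ± 87.0 while the gene's median was -2.33. CCN3 probeset 3113215 went from 1564 ± 57.5 to 1106 ± 42.4 against -2.11, and TFF1 probeset 3933564 from 135 ± 55.8 to 187 ± 29.9 against 2.57. In 31 of the 45 genes the most different probeset moved less than its gene or against it, and in 14 further than it. The diffSplice count was 758 without the filter on dim features, 1048 with the replicate block and 248 by its F test, and the splicing index called 1 gene. It fell to 281 without control replicate 1, 228 without control replicate 2 and 222 without knockdown replicate 2.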

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

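The thresholds of at least 2-fold, the list test on exon-level medians, exon usage in genes that moved little and exon usage with own variances were chosen after the data were seen, as were the settings run on the exon-level medians of single genes. ITGA3 kept its fall in the main limma fit and its 12 alternative settings, with log2 differences from -2.35 to -2.47. It did not pass the plain per-gene test, which called 0 clusters. Over 111 other genes taken by the rule for named genes or named besides, and the 12 settings of the limma fit, 1215 of 1304 values kept their direction and side of the threshold, 78 lost the call, 9 gained it and 2 changed sign. Both sign changes were of FBLN2, which never passed, at -0.056 without control replicate 1 and -0.389 without knockdown replicate 1, against up to 0.470 without knockdown replicate 2. Signal over background is not given in the sources used here, and counts changed with the filter on dim features.

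Without the filter on dim features, 485 clusters were higher, 43 probesets higher and 120 lower, 758 genes were called for exon usage, and the gene-level and exon-level changes correlated at 0.934. Leaving out the lower 60% gave 5 shifted lists, with the mesenchymal (adjusted p = 0.0220) and WNT and TGF-beta lists (0.0208) added. Without the intensity trend, 379 probesets were higher and 1314 lower. Higher clusters numbered 1351 after quantile normalization and 1586 after centring. The labels do not say whether same-numbered arrays were handled together. Deviations of same-numbered arrays from their group means correlated at 0.290 across clusters and 0.300 across probesets. That leaves a pairing possible, and 2 pairs cannot settle it. With the replicate block, 1324 clusters were higher, 10755 probesets higher and 18202 lower, and 1048 genes were called for exon usage. A plain per-gene test called 0 higher and 0 lower, though 3288 clusters had an unadjusted p under 0.05, against 4726 by limma. limma's treat against a 1.2-fold change called 146 and 464, and a change of at least 2-fold left 61 and 146. Camera with an estimated correlation called 0 lists, and fry, which does not compare a list with other genes, called 14. Among them was the integrin list, downward (adjusted p = 0.0220) and opposite to its camera direction. That list includes ITGA3, the target of the hairpin, so its fry call is not independent of the knockdown itself. For exon usage, the diffSplice F test called 248 genes, the splicing index 1 and own variances 49. A refit to the genes with a median under 0.5 alone called 120, where the fit to all genes called 225 among the genes with such a median. The cause of these differences was not tested, apart from the smaller sets of features.

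Leaving out each array in turn gave 166 to 909 higher and 632 to 1906 lower clusters, 753 to 2110 higher and 2161 to 3257 lower probesets, 222 to 350 genes for exon usage, 2 to 4 lists, and correlations from 0.956 to 0.968. The lone array of a group was then assumed to vary like the other group.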

Other observations

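The exon-level medians of single genes below, S100P and CDH1 were chosen after their values were seen, and the test of probeset brightness, the count of probesets passing on their own and the count over other splits of the arrays were specified after the results they bear on. Some listed genes had no tested gene-level cluster of their own and were read as the median over their exon-level probesets (limma, adjusted over genes). In cholesterol synthesis, FDFT1, which encodes squalene synthase, differed by -0.85 ± 0.10 (SE) on the log2 scale (adjusted p = 0.00172), CYP51A1, lanosterol demethylase, by -0.71 ± 0.10 (0.00386) and SREBF2, the transcription factor of the pathway, by -0.56 ± 0.12 (0.0184). The glucose transporter gene SLC2A3 was higher by 0.73 ± 0.10 (0.00343). Of inflammatory genes, the chemokine gene CXCL1 (-1.17 ± 0.11, 0.000501) and IL24 (-1.78 ± 0.21, 0.00176) were lower, and BIRC3, an inhibitor of apoptosis, was higher (1.23 ± 0.16, 0.00223). The cytoskeletal genes TAGLN (-1.35 ± 0.15, 0.00127) and FLNA, which encodes filamin A (-0.59 ± 0.10, 0.00623), were lower. CDH1, the gene of E-cadherin, was higher by 1.51 ± 0.15 (0.000633), with the median taken in each array, but the median of its 5 probesets' own differences was 0.58, 2 of them were called, and its probeset 3666411 went from 994 ± 125 to 779 ± 262 (diffSplice adjusted p = 0.0392 for the gene, 0.0532 with own variances). Of 37 ribosomal protein genes read only this way, 3 were lower, 0 higher and 34 did not pass. RPS27 differed by -0.69 ± 0.10 (0.00389), RPS18 by -0.39 ± 0.09 (0.0281) and RPS9 by -0.37 ± 0.10 (0.0473). RPS18 lost its call without any 1 array (adjusted p = 0.0596 to 0.176), without the intensity trend (0.0919) and after centring (0.0525). RPS9 lost it without control replicate 2 (0.173), knockdown replicate 1 (0.134) or 2 (0.167), the filter (0.0594) or the trend (0.124), and after quantile normalization (0.0691) or centring (0.0717). SREBF2 lost its call without control replicate 1 (adjusted p = 0.0631), control replicate 2 (0.0540) or knockdown replicate 2 (0.129).

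More clusters fell (2016) than rose (791) in knockdown, or 71.8% of the calls. A difference in overall brightness between the arrays may account for that excess. On the deposited scale, 61 of the higher and 146 of the lower clusters changed at least 2-fold, counts that were not repeated after rescaling. The lower share was 47.9% after centring each array on its median and 55.3% after quantile normalization. Centring moved the median log2 difference by 0.098 and quantile normalization by 0.072. Either scaling moves the share towards an even split whatever the cause, so these values do not decide, and brightness and a real excess of falls cannot be told apart. An effect of α3 loss on many genes stays open and was not tested.

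diffSplice called 14.9% (203 of 1367) of genes whose probesets moved by a median of at least 0.5 on the log2 scale, and 2.08% (225 of 10844) of the other genes. Dim probesets might move less than their gene. The most different probeset moved less than its gene or against it in 86.7% (176) of the former calls, above the share set beforehand for dimness, but the same way and less in 19.2% (39). In the other 137 it moved against its gene, and 3 of these passed limma on their own, which does not show that the rest stayed level. Of 153 probesets that moved less or against in genes that fell, 61.4% were dimmer in controls than the median probeset of their gene (exact binomial 95% interval 53.2 to 69.2%). Dimness and altered splicing cannot be told apart. The difference in calls was predicted for dimness, but it sorts genes by size of change and not by brightness. Any probeset that does not follow its gene would add to it. The share that moved less goes with dimness only with the 137 counted in. The share that was dimmer lies between the values that would bear dimness out or exclude it. Other reasons for a probeset not to follow its gene were not tested. Altered splicing was not tested apart from these calls.

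TFF1 and S100P, a calcium-binding protein gene that went from 211 ± 4.99 to 591 ± 26.3 (adjusted p = 0.000920), are often high in luminal breast cells, and cells of a luminal line in the knockdown cultures could raise them. Without the filter on dim features, 485 of 22011 clusters were called higher. Over 18 other luminal markers in that fit, the median log2 difference was -0.037. Of these markers 11.1% were called higher, a larger share than over all clusters. Both values lay below the bounds set beforehand, which argues against a large share of such cells. Markers already bright in controls, such as KRT8 (4078) and KRT18 (4520), are a weak gauge of added cells. The 2 called higher were CDH1 (27.1 to 172) and TFF3 (175 to 245, adjusted p = 0.0461), whose call in the filtered fit was lost without control replicate 1 (0.0588) or knockdown replicate 1 (0.152) or 2 (0.161). FOXA1 measured 123 ± 8.59 and 123 ± 22.6, and ESR1 measured 77.6 and 73.6 at the gene level but differed by 0.37 ± 0.17 (SE, adjusted p = 0.183) as an exon-level median. A small share of such cells is not excluded, and a change in the cells' own TFF1 and S100P expression stays open as a hypothesis.

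With 2 arrays per group there are 3 splits of the 4 arrays. The real one called 2807 clusters by limma, the highest of the others 0, and 1 of the 3 reached the real count. Splits so few cannot give a share under 0.05.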
